A study of Mus musculus with 12 samples.

How the data were processed

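Expression was measured on single-colour Illumina mouse bead arrays in 12 samples, 4 each of bone marrow mesenchymal stem cells, heart-derived cells and kidney-derived cells. Per the labels, total RNA was extracted with a Qiagen kit without DNase treatment and amplified and biotin-labelled with an Illumina kit. Culture conditions, passage, mouse strain and donor sex are not given in the sources used here. The series design text calls the 4 samples per tissue biological replicates and says nothing of animals, litters or days, so p-values measure the spread between these samples.

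The deposited table of raw values holds, per the file headers, non-normalized probe intensity for each array, which is neither background-subtracted (lowest value 72.3) nor scaled between arrays (array medians 129.8 to 149). Beside each intensity the deposited table holds a detection fraction between 0 and 1, headed as a detection p-value, which rises with the signal and is 1 for bright probes, so it was read as 1 minus a detection p. The table has 45281 entries under 35746 distinct probe identifiers, of which 6798 identifiers repeat, and each entry was kept as a probe of its own. A second deposited table holds the authors' processed intensity on a linear scale for 35739 identifiers. Per the submitters' processing notes the tool was lumi, with settings not given in the sources used here. Its medians are 18.8 to 19 on every array, and within an array its ranks match those of the raw values (rank correlation 1). It was used only as an alternative. The base of its background reduction stays unknown. Gene names came from the platform annotation table, in which 26385 identifiers have 1 symbol, 18 have several and 9343 are not listed and are unnamed here. No genome build is stated, so no coordinates are given, and RefSeq names of assembly GRCm38.p6 served only to look up symbols.

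Raw intensities were processed with limma 3.58.1 in R 4.3.3. Background correction and quantile normalization used neqc with detection p-values and an offset of 16, followed by log2. A probe was kept if its detection fraction exceeded 0.95 on at least 4 of the 12 arrays, which left 20649 probes, 17315 of them named. The kept probe with the highest mean over all arrays stood for a gene, giving 10797 genes, of which 4351 had several kept probes. Among genes called in a comparison with several kept probes, a further probe was called in the opposite direction for 67 of 2703 (heart minus bone marrow), 42 of 2175 (kidney minus bone marrow) and 37 of 2385 (kidney minus heart). The number of arrays limits the precision.

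A linear model with a mean per tissue was fitted to all 12 arrays (lmFit, eBayes with trend), so that the tissues share 1 estimate of spread, and 3 contrasts and an F test were taken. Calls are two-sided at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and, beside it, an estimated correlation, with adjustment over the 27 of 31 lists that had at least 5 tested genes. The rotation test fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes, gave 22, 22 and 18 lists past the threshold in heart minus bone marrow, kidney minus bone marrow and kidney minus heart. A mean rise or fall of every list past camera had the sign of its median. Similarity of arrays was tested by exact permutation of tissue labels. Where all probes of a gene were undetected on every array of the dimmer tissue, or that tissue's mean on the probe used lay below the mean detection floor, a lower bound replaced the fold change. It sets the bright tissue's mean against the mean over the dim arrays of the higher of the lowest detected signal and the probe's own value.

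The groups, comparisons with their tests, gene lists, alternatives and naming rule were fixed before the data were examined, except for the alternative and the tests of explanations said to be chosen later. The rule allowed, per comparison, the 6 largest rises and falls among genes past the threshold, separated between tissues and detected throughout the higher tissue, up to 4 members per list past the threshold, a fixed set of surface genes, markers and developmental factors, and the 6 most restricted genes per tissue. Not every gene the rule allows is named, and the choice among them was made after their values were seen. Genes outside the rule are said to be so where a change is given. Some others outside it, such as Kdr, Vwf and Pax8, are named only for their detection.

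The fit was tested on simulated data with 10797 genes and independent noise. In each comparison 67, 67 and 66 genes were changed by a log2 of 0.5, 1 and 2. Far more genes were called in the real data, so the shares given here need not hold there. For heart minus bone marrow the fit recovered 55.2% of genes changed by a log2 of 0.5, 94% at 1 and 100% at 2, with 6.2% false among calls. For kidney minus bone marrow the shares were 52.2%, 98.5% and 100% with 5.6% false, and for kidney minus heart 49.3%, 98.5% and 100% with 4.6% false. The alternatives covered background correction, normalization, the deposited processed values, detection filters, choice of probe, replicate block, samples in the fit, array weights, moderation, threshold and each array left out. With every kept probe tested on its own, a named gene was represented by the probe that moved least in its direction. A direction was compared only where the result passed in either setting. Labels give tissues the same replicate numbers without saying that a number marks a shared animal or day. Same-numbered arrays had correlations of their deviations from -0.2 to 0.13, with 1 of 12 pairs above 0.1, so arrays were not paired. Figures were drawn with matplotlib 3.10.9.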

Results

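Gene expression was measured in cultured mouse cells from 3 tissues on single-colour Illumina bead arrays, which report 1 signal per probe. Bone marrow gave mesenchymal stem cells (MSC), fibroblast-like cells that can form bone, fat and cartilage, and heart and kidney gave cells that the labels describe as resembling them. Each tissue was represented by 4 arrays, which the series describes as biological replicates, and each array carried total RNA. Mean raw signal was 754 to 950 on the bone marrow arrays, lowest on bone marrow replicate 1, against 935 to 1066 for heart and 1004 to 1049 for kidney. Between 18635 and 19792 of 45281 probes were detected per array, and 10797 named genes entered the tests. The Y-linked genes Eif2s3y, Kdm5d and Uty were each detected by a probe on all 12 arrays, while Xist, the RNA that silences an X chromosome, was detected on 1. The number of arrays limits the precision of every value. Changes below are log2 fold changes ± SE from limma with 4 arrays per tissue, and adjusted p-values are Benjamini-Hochberg values over all genes unless stated otherwise. Each gene said to have risen or fallen had all 4 arrays of the higher tissue above all 4 of the lower tissue, unless stated otherwise. Where no probe of a gene was detected on any array of the dimmer tissue, or that tissue's mean on the probe used lay below the mean detection floor, the change is given as a lower bound ("at least"), set against the higher of that array's detection floor and the probe's own signal.

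The question of how alike the 3 populations are was first asked over all genes. Of the 10052 genes detected on all 4 arrays of at least 1 tissue, 8544 (85%) were detected on all 12 arrays, and 15 were detected on all bone marrow arrays and on 0 arrays of both other tissues, against 99 for heart and 27 for kidney. Of the 9053 genes detected throughout bone marrow, 95.9% were also detected throughout heart and 96.6% throughout kidney. Array values correlated at a mean r of 0.99 within bone marrow and 0.994 within both heart and kidney. Between tissues the mean was 0.936 for bone marrow and heart, 0.959 for bone marrow and kidney, and 0.95 for heart and kidney, all across genes, which are not independent replicates. The excess of within-tissue over between-tissue correlation was 0.0443, and the true grouping gave the highest of all 5775 groupings of the arrays (exact permutation p = 0.000173, one-sided, the smallest possible). Tissue accounted for 84.6% of the variance. By limma's F test 7376 of 10797 genes (68.3%) differed between tissues, with a median residual SD of 0.171.

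**Figure D1:**
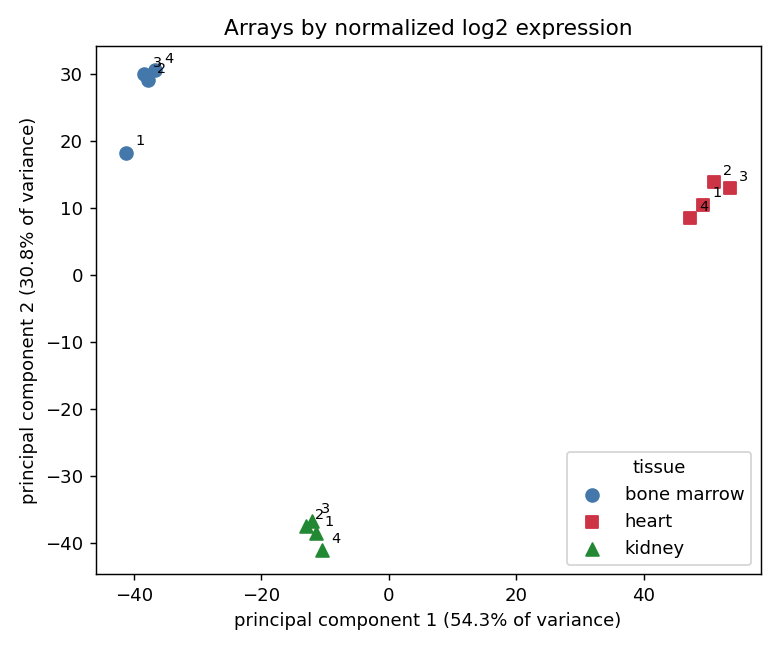
The 12 arrays on the first 2 principal components of the normalized log2 values (x axis, 54.3% of variance; y axis, 30.8%), coloured by tissue, with replicate numbers beside the points. The 3 tissues form separate groups, and bone marrow replicate 1 lies at 18.24 on the y axis, below the other bone marrow arrays.

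Most of the classical MSC surface genes were detected in all 3 populations. Of 19 panel genes with a named probe, 15 were detected on all 4 bone marrow arrays, 17 on all heart arrays and 16 on all kidney arrays. Cd44, Thy1, Eng and Itgb1, which encode antigens used to define MSC, and both platelet-derived growth factor receptors, Pdgfra and Pdgfrb, were detected on all 12 arrays. Nt5e, which encodes the ectonucleotidase CD73, was detected on 4 heart arrays, 1 kidney array and 0 bone marrow arrays. Ptprc and Itgam, surface genes of blood cells, and Kit, a receptor of hematopoietic progenitors, were detected on 0 arrays, whereas Cd14, Cd3e and Cd80, the only 3 of 14 genes of this non-MSC panel detected on all 4 arrays of any tissue, were detected on all 12. Also detected on 0 arrays were the endothelial genes Kdr and Vwf, the myeloid adaptor Tyrobp, the epithelial genes Epcam and Krt18, the mesothelial gene Msln and the atrial and cardiac myosin genes Myl7 and Myh6. Of the macrophage and monocyte list, 7 of 23 genes with a probe were detected on all 4 arrays in bone marrow, 7 in heart and 7 in kidney, not the same genes throughout, since Trem2 was detected on 4 bone marrow, 3 heart and 0 kidney arrays. For the cardiomyocyte list the counts were 2 of 19 in bone marrow and 4 in both heart and kidney. Of the 20 renal epithelial genes 6 were detected on all 4 arrays in bone marrow, 7 in heart and 8 in kidney. Of the 21 endothelial genes, 5, 6 and 7 were, in the same order, and of the 17 mesothelial and epicardial genes 5, 9 and 9. The epithelial keratin gene Krt8 was detected on all 12 arrays, and the epithelial cadherin gene Cdh1 on 4 bone marrow, 3 heart and 4 kidney arrays. The endothelial cadherin gene Cdh5 was detected on 1 heart and 1 kidney array. Upk3b, a mesothelial gene, was detected on 1 bone marrow and 2 heart arrays.

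**Figure D2:**
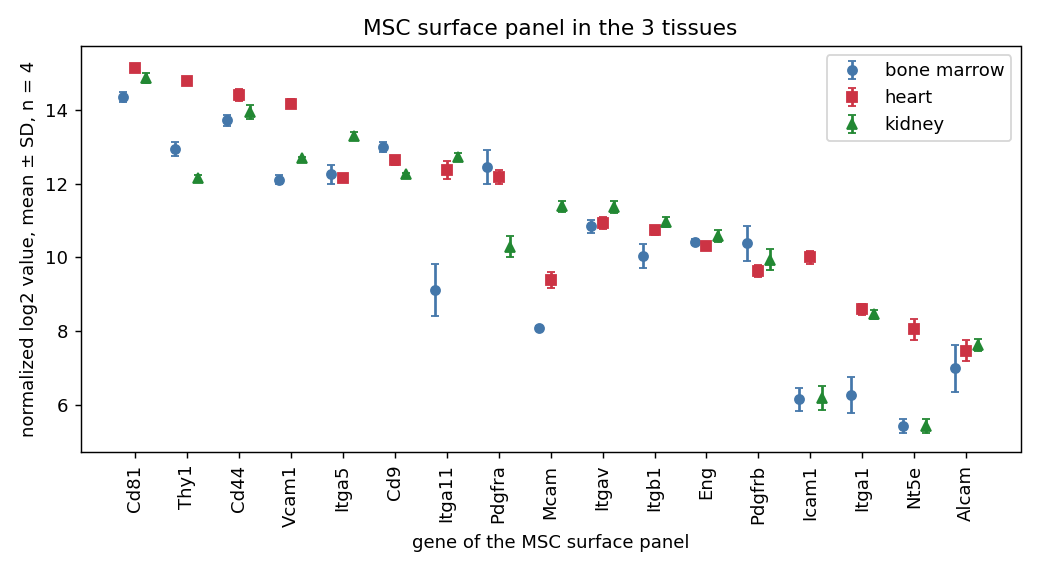
Normalized log2 values (y axis) of the 17 tested genes of the MSC surface panel (x axis) as mean ± SD over 4 arrays per tissue. Icam1 and Nt5e were highest in heart cultures and Mcam in kidney cultures, while differences of Pdgfrb and Alcam between tissues were smaller, though some passed the threshold.

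The comparison of heart-derived cells with bone marrow MSC asked how the heart population departs from the classical one. Cck, which encodes the peptide hormone cholecystokinin, was at least 248-fold higher in heart cells (adjusted p = 2.74e-19). The serine protease inhibitor gene Serpina3n was at least 224-fold higher, and Serping1, which encodes the complement C1 inhibitor, rose by 6.32 ± 0.33. Esm1, a secreted proteoglycan gene, rose by 6.37 ± 0.26, Rspo3, a potentiator of Wnt signalling, was at least 48.9-fold higher, and the neuronal adhesion gene Slitrk5 at least 36.2-fold higher. Falls included the Hox genes Hoxc9 (at least 50-fold lower) and Hoxc10 (at least 14-fold lower), the interferon-induced gene Oasl2 (-4.21 ± 0.41), the lipoprotein lipase gene Lpl (-4.15 ± 0.16) and the chemokine gene Ccl9 (-4.04 ± 0.24). Of 10797 genes, 6042 passed the threshold in this comparison, 2846 higher and 3196 lower in heart cells. A change of at least 2-fold was reached by 908 genes upward and 604 downward, 1512 in all, or 899 without background correction and 981 among genes with probes detected on all 12 arrays. Of 27 gene lists fixed in advance, 9 passed limma's camera test with a preset gene-gene correlation, and 1 of them, smooth muscle, with an estimated correlation. The member counts of those 9 lists were the same when adjusted over the list alone.

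Hox genes, the transcription factors that mark position along the body axis, moved in both directions. All 8 tested members of paralogue groups 1 to 5 were higher in heart cells, including Hoxb2 (at least 19.4-fold higher), Hoxa5 (3.04 ± 0.07), Hoxb5 (3.90 ± 0.21) and Hoxb4 (at least 21.3-fold higher), with adjusted p = 1.38e-07 for the list and adjusted p = 0.0583 with an estimated correlation. Of the 15 tested members of groups 6 to 13, 8 were lower, 2 were higher and 5 did not pass (adjusted p = 0.0143; adjusted p = 0.0831 with an estimated correlation). Hoxd8 was at least 9.58-fold lower and Hoxa10 at least 2.2-fold lower, whereas Hoxb7 rose by 4.09 ± 0.10.

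Contractile and smooth muscle genes were higher in heart cells for 14 of 16 tested members, with none lower (adjusted p = 2.32e-08; 0.0173 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, was at least 10.2-fold higher and the intermediate filament gene Des at least 4.41-fold higher, while Mylk, which encodes myosin light chain kinase, rose by 3.55 ± 0.21 and Tagln, an actin-binding gene, by 1.97 ± 0.09. Acta2, smooth muscle actin, showed 0.01 ± 0.06 on its brightest probe, whose signals of up to 60714.2 lay near the highest on the arrays (64071.3), so that equality on this probe carries little information. Of the 5 kept Acta2 probes, 3 were higher in heart and 3 in kidney cells than in bone marrow. The largest rises on probes with bright signals in every tissue were 0.59 and 1.04, and 1 of the kidney rises was on a probe with a mean raw signal of 136 in bone marrow, near background. Among MSC surface genes 10 of 17 were higher and 2 lower (adjusted p = 0.00102; adjusted p = 0.0583 with an estimated correlation), including the adhesion gene Icam1 (3.85 ± 0.17), the integrin gene Itga11 (3.27 ± 0.22), Nt5e (at least 5.25-fold higher) and Thy1 (1.86 ± 0.08).

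Cell division genes moved the other way. In the proliferation list 21 of 22 tested genes were lower in heart cells and 1 was higher, 15 of them by at least 2-fold (adjusted p = 1.19e-09; adjusted p = 0.0893 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, fell (-1.77 ± 0.14), as did the replication helicase gene Mcm5 (-1.52 ± 0.10), the topoisomerase gene Top2a (-1.34 ± 0.10) and the mitotic kinesin gene Kif11 (-1.32 ± 0.10). Genes of the hypoxia and glycolysis list were higher for 12 of 15 members and lower for 3 (adjusted p = 0.0015; adjusted p = 0.0934 with an estimated correlation), including Adm, which encodes the vasodilator adrenomedullin (2.82 ± 0.15), Ankrd37 (2.71 ± 0.24) and the stress-response gene Ndrg1 (1.83 ± 0.15). Interferon response genes were lower in heart cells for 15 of 18 members and higher for 1 (adjusted p = 0.000233; adjusted p = 0.469 with an estimated correlation). These included Rsad2 (-3.36 ± 0.26), Isg15 (-3.33 ± 0.32) and the chemokine gene Cxcl10 (at least 7.16-fold lower). The mean log2 value of this list was 8.268 on bone marrow replicate 1 and 9.71 to 10.228 on the other 3 bone marrow arrays, against 7.581 to 7.845 on the heart arrays.

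BMP and TGF-beta signalling genes were higher for 12 of 20 members and lower for 6 (adjusted p = 0.0254; adjusted p = 0.0831 with an estimated correlation). This list did not pass on the authors' deposited values (adjusted p = 0.0593), without the detection filter (0.0524) or with only probes detected on all 12 arrays (0.0938). The members that rose most included secreted inhibitors of the pathway, Fst (3.75 ± 0.11), Grem1 (3.71 ± 0.09) and Chrd (2.57 ± 0.19). Imprinted genes, expressed from 1 parental copy, were higher for 7 of 12 members and lower for 1 (adjusted p = 0.0123; adjusted p = 0.0831 with an estimated correlation). The growth factor adaptor gene Grb10 rose by 4.54 ± 0.09 and Peg3 was at least 11.7-fold higher, while Dlk1, an inhibitor of fat cell formation, fell (-2.77 ± 0.09). The remaining 18 lists did not pass (adjusted p from 0.0701 to 0.931), although single members differed. The osteoblast factor gene Sp7 was at least 4.76-fold lower and the fat cell regulator Pparg fell (-1.99 ± 0.17). Cardiac transcription factor genes were higher for 9 of 17 members and lower for 3 (adjusted p for the list = 0.0701), with Isl1 at least 8.23-fold higher, Mef2c at least 14.2-fold higher and Irx5 lower (-3.77 ± 0.13). Of the 24 cardiac factor genes with a named probe, 10 were detected on all bone marrow arrays, 14 on all heart arrays and 12 on all kidney arrays. Tbx20 and Hand2 were detected on 0 arrays. Gata4 was detected on 4 bone marrow, 2 heart and 4 kidney arrays, and Tbx5 on 1, 4 and 0. Tcf21, a factor of epicardial and renal stroma, was at least 6.5-fold higher, Fgf2 rose by 3.26 ± 0.17 and Fgf10 was at least 21.6-fold higher. Lyz2, a myeloid lysozyme gene, rose by 0.67 ± 0.18 while 4 of 8 tested macrophage genes were higher and 2 lower (adjusted p for the list = 0.408).

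**Figure D3:**
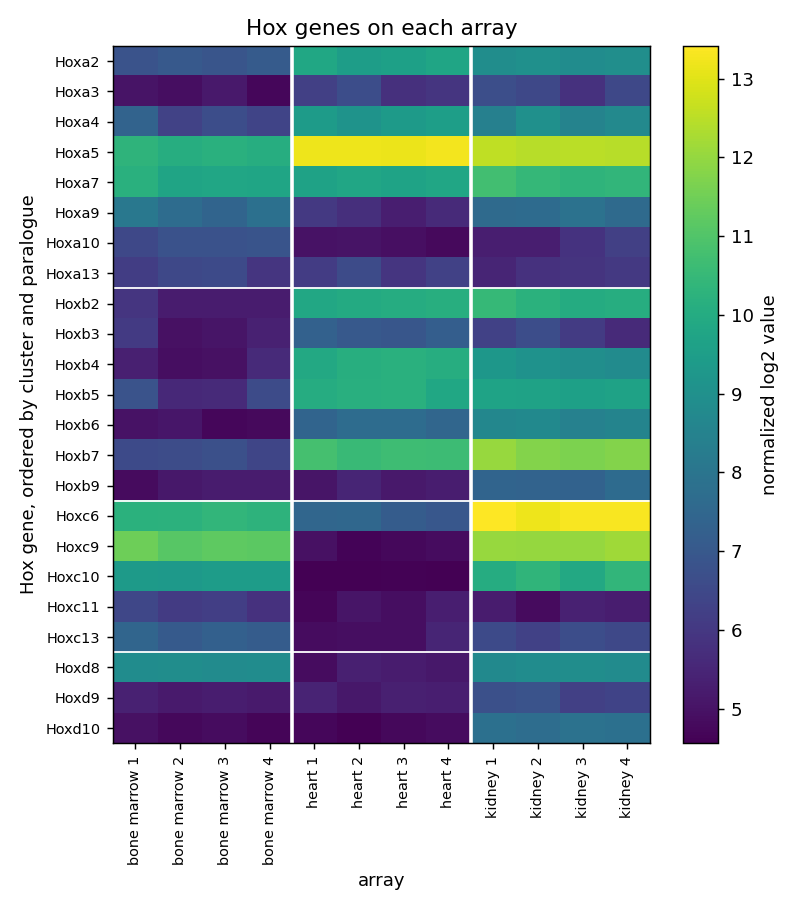
Normalized log2 values (colour) of the 23 tested Hox genes on each of the 12 arrays, with tissues separated by vertical lines and Hox clusters by horizontal lines. Hoxb genes were dim in bone marrow, and Hoxc9 and Hoxc10 were dim in heart and bright in bone marrow and kidney.

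The same question was asked of kidney-derived cells against bone marrow MSC. Mylk rose by 5.71 ± 0.21 (adjusted p = 2.5e-14), and Des was at least 27.3-fold higher in kidney cells. Ankrd1, a muscle ankyrin repeat gene, rose by 5.16 ± 0.10, Ccdc68 was at least 28.4-fold higher, Hoxb7 rose by 5.24 ± 0.10 and Hoxb2 was at least 22.4-fold higher. Falls included Dio3, which encodes a deiodinase that inactivates thyroid hormone (-5.46 ± 0.26), the cell cycle regulator gene Rgcc (-5.24 ± 0.20), the haptoglobin gene Hp (at least 19.1-fold lower), the interleukin-1 receptor antagonist gene Il1rn (at least 17.3-fold lower) and the interferon-induced gene Rsad2 (-4.02 ± 0.26). In all, 4769 of 10797 genes passed, 2150 higher and 2619 lower in kidney cells, of which 529 and 384 changed by at least 2-fold, 913 in all, or 526 without background correction and 581 with probes detected on all 12 arrays. Of the 27 lists, 10 passed camera with the preset correlation and 3 with an estimated one, namely smooth muscle and both Hox lists.

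Of the 16 smooth muscle genes 14 were higher and 0 lower (adjusted p = 3.82e-14; 0.0022 with an estimated correlation), among them Actg2, enteric smooth muscle actin (3.36 ± 0.07), Myh11 (at least 12-fold higher) and Tagln (2.77 ± 0.09). Both Hox lists were higher. All 8 members of paralogue groups 1 to 5 were higher (adjusted p = 4.8e-09; 0.0322 with an estimated correlation), and of groups 6 to 13 there were 9 of 15 higher and 3 lower, or 9 and 4 adjusted over the list alone (adjusted p = 0.000664; 0.0322 with an estimated correlation). Hoxc6 rose by 3.03 ± 0.11, Hoxb6 was at least 7.69-fold higher and Hoxd10 at least 4.46-fold higher. MSC surface genes were higher for 9 of 17 members and lower for 3, or 10 and 4 adjusted over the list alone (adjusted p = 0.0203; adjusted p = 0.125 with an estimated correlation). Mcam, an adhesion gene of perivascular cells, rose by 3.29 ± 0.11 and Itga11 by 3.62 ± 0.22, while Pdgfra fell (-2.15 ± 0.17) and Thy1 fell (-0.77 ± 0.08).

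Interferon response genes were lower in kidney cells for 17 of 18 members and higher for 0 (adjusted p = 3.36e-08; adjusted p = 0.277 with an estimated correlation), including the antiviral genes Ifit3 (-3.18 ± 0.30) and Oasl2 (-3.51 ± 0.41) and the GTPase gene Igtp (-3.21 ± 0.33). The list's mean log2 value was 7.275 to 7.461 on the kidney arrays, below bone marrow replicate 1 (8.268) and the other bone marrow arrays. Proliferation genes were lower for 14 of 22 members, none by 2-fold (adjusted p = 0.000664; adjusted p = 0.277 with an estimated correlation), with Kif11 at -0.72 ± 0.10 and Mcm5 at -0.60 ± 0.10. Adipogenic genes were lower for 7 of 11 members and higher for 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.00862; adjusted p = 0.125 with an estimated correlation), including Lpl (-2.02 ± 0.16) and the lipid droplet gene Plin4 (-1.85 ± 0.13). Pparg showed -0.11 ± 0.17 and did not pass (adjusted p = 0.624). Basement membrane genes were higher for 9 of 16 members and lower for 1, or 10 and 1 adjusted over the list alone (adjusted p = 0.00688; adjusted p = 0.386 with an estimated correlation), including the collagen IV gene Col4a5 (1.26 ± 0.09). The mean log2 values of this list overlapped, with 9.598 to 10.222 on the bone marrow arrays, lowest on replicate 1, and 10.191 to 10.467 on the kidney arrays.

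The cardiac transcription factor list was higher for 9 of 17 members and lower for 3 (adjusted p = 0.01; adjusted p = 0.078 with an estimated correlation), and its movers included Hey2 (at least 3.21-fold higher), Foxc2 (1.78 ± 0.15) and Mef2c (at least 2.45-fold higher). Imprinted genes were higher for 6 of 12 members and lower for 1 (adjusted p = 0.00862; adjusted p = 0.0896 with an estimated correlation), with Grb10 at 3.80 ± 0.09 and the cell cycle inhibitor gene Cdkn1c at 1.20 ± 0.19. With the mean of a gene's probes in place of the brightest, neither the cardiac list (adjusted p = 0.063) nor the imprinted list (0.0547) passed. The remaining 17 lists did not pass (adjusted p from 0.0588 to 0.907). Among their members, Bmp4 was at least 8.16-fold higher, Sfrp1, which encodes a Wnt inhibitor, fell (-3.44 ± 0.32), Hgf, hepatocyte growth factor, fell (-3.74 ± 0.11), and the marrow niche chemokine gene Cxcl12 fell (-1.21 ± 0.18). The collagen VI genes Col6a1 (-2.51 ± 0.21) and Col6a2 (-3.38 ± 0.26) also fell. Renal transcription factor genes were higher for 3 of 10 members and lower for 4 (adjusted p for the list = 0.735). Gata3 was at least 4.87-fold higher and Osr1 fell (-1.37 ± 0.15), while Pax2, Pax8 and Hoxa11 were detected on 0 arrays. Of the markers of other cell types, the endothelial genes Emcn (at least 7.96-fold higher) and Flt1 (2.90 ± 0.10) rose, and 3 of 10 tested endothelial genes were higher and 2 lower (adjusted p for the list = 0.149). The proximal tubule receptor gene Lrp2 was at least 4.28-fold higher, and in heart cells at least 2.93-fold higher than in bone marrow, with 2 of 8 renal epithelial genes higher and 0 lower (adjusted p for the list = 0.132) in kidney. Of the macrophage genes Trem2 was at least 2.13-fold lower and Cd14 fell (-1.46 ± 0.12), with 2 of 8 lower and 0 higher (adjusted p for the list = 0.397).

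**Figure D4:**
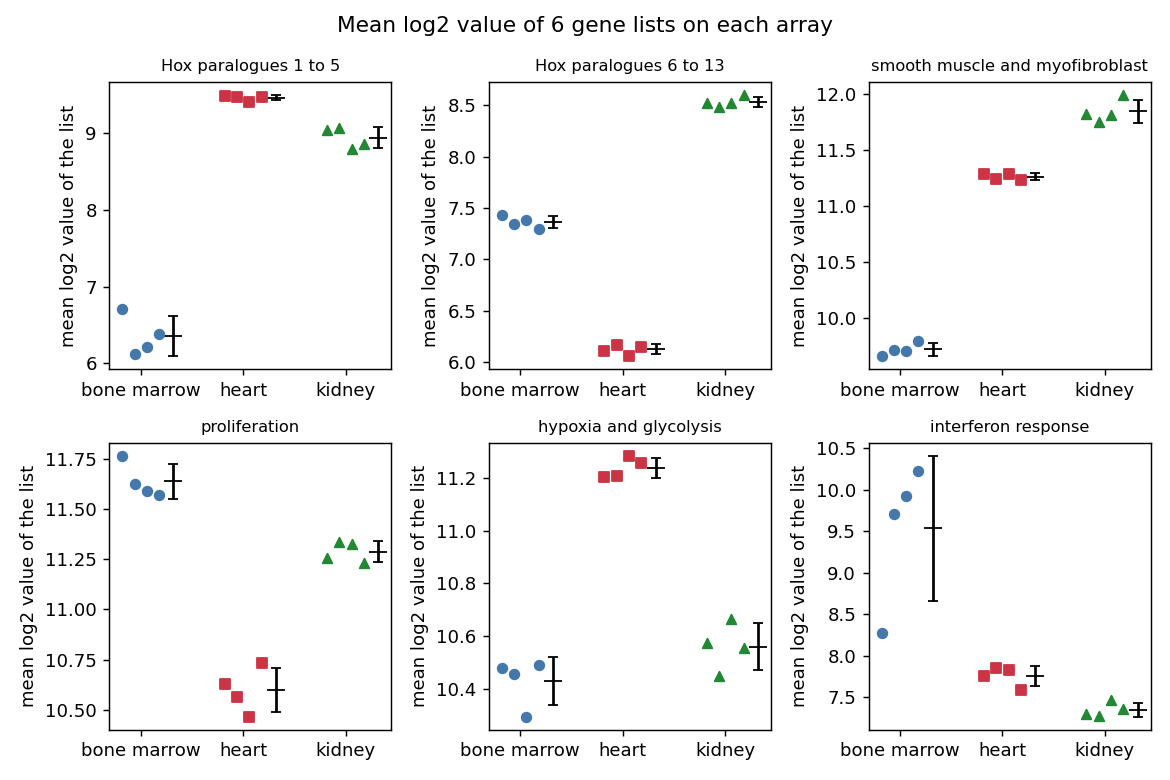
Mean normalized log2 value (y axis) of the tested members of 6 gene lists on each array, by tissue (x axis), with the mean ± SD over 4 arrays beside the points. Interferon response genes were lowest within bone marrow on replicate 1 (8.268), and proliferation genes were lowest in heart (10.467 to 10.732).

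The direct comparison of kidney with heart cells tests where the populations from solid organs differ. Hox genes were among the rises, with Hoxc9 at least 87.7-fold higher in kidney cells (adjusted p = 7.58e-21), Hoxc6 at 6.05 ± 0.11 and Hoxc10 at least 23.9-fold higher. The homeobox gene Gbx2 and the G protein regulator gene Rgs4 were both at least 16.6-fold higher, and Pcolce2, a procollagen-processing enhancer, rose by 4.62 ± 0.13. Serpina3n was at least 240-fold lower in kidney cells and Serping1 at least 115-fold lower. Ednrb, an endothelin receptor gene, was at least 33.6-fold lower, Slitrk5 at least 37.9-fold lower, the T-box factor gene Tbx4 at least 32.3-fold lower and the complement regulator gene Cd55 at least 31.9-fold lower. The threshold was passed by 5290 genes, 2685 higher and 2605 lower in kidney cells, with 417 and 751 at 2-fold or more, 1168 in all, or 659 without background correction and 726 with probes detected on all 12 arrays. Of 27 lists 4 passed camera with the preset correlation and 1, the list of Hox groups 6 to 13, with an estimated correlation. For this number of lists 10 of 35 splits of the 8 arrays, the real one included, gave as many.

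Of 15 Hox genes of paralogue groups 6 to 13, 13 were higher in kidney cells and 0 lower, or 13 and 1 adjusted over the list alone (adjusted p = 2.1e-09; 0.00186 with an estimated correlation). Groups 1 to 5 were lower for 5 of 8 members without passing as a list (adjusted p = 0.102), with Hoxb4 at -1.06 ± 0.15. Proliferation genes were higher in kidney cells for 20 of 22 members and lower for 1, or 21 and 1 adjusted over the list alone (adjusted p = 5.11e-08; adjusted p = 0.307 with an estimated correlation), including Rrm2 (1.66 ± 0.14) and Mcm6 (1.05 ± 0.08). Hypoxia and glycolysis genes were lower for 10 of 15 and higher for 2 (adjusted p = 0.0101; adjusted p = 0.307 with an estimated correlation), including Adm (-2.72 ± 0.15), Ndrg1 (-2.44 ± 0.15) and the glucose transporter gene Slc2a1 (-1.05 ± 0.07). Smooth muscle genes were higher for 9 of 16 and lower for 1 (adjusted p = 0.00853; adjusted p = 0.279 with an estimated correlation), with Des at 2.63 ± 0.12 and Actg2 at 2.16 ± 0.07.

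The other 23 lists did not pass (adjusted p from 0.0522 to 0.995). The lowest of these was the macrophage and monocyte list, with 6 of 8 members lower in kidney cells and 0 higher, among them Cd14 (-1.11 ± 0.12) and Lyz2 (-0.98 ± 0.18). Interferon response genes were lower for 6 of 18 and higher for 2 (adjusted p = 0.452). In the MSC surface panel, 4 genes were higher and 8 lower (adjusted p = 0.314). Icam1 (-3.82 ± 0.17), Thy1 (-2.63 ± 0.08), Nt5e (at least 5.42-fold) and Pdgfra (-1.89 ± 0.17) were lower in kidney cells, while Mcam (2.00 ± 0.11) and Itga5 (1.15 ± 0.10) were higher. Cardiac transcription factor genes were higher for 8 of 17 members and lower for 7 (adjusted p = 0.867), with Isl1 at least 8.62-fold lower, Tcf21 at least 6.81-fold lower and Irx3 (2.90 ± 0.13) and Irx5 (3.12 ± 0.13) higher. Renal transcription factor genes were higher for 3 of 10 and lower for 4 (adjusted p = 0.488), with Osr1 (-2.89 ± 0.15) and Osr2 (-3.14 ± 0.14) lower. Among single genes of further lists, Fgf10 (at least 22.2-fold), Hgf (-3.24 ± 0.11), Grem1 (-4.18 ± 0.09) and Rspo3 (-5.33 ± 0.21) were lower in kidney cells, and Bmp4 (2.10 ± 0.16), Tgfb2 (2.06 ± 0.12) and Wnt2 (at least 5.23-fold) were higher. Of 20 matrix protease genes 5 were higher and 8 lower (adjusted p = 0.814), and Mmp3 was lower (-3.22 ± 0.21) while Mmp13 (3.04 ± 0.13) and Htra1 (3.17 ± 0.08) were higher.

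Genes restricted to 1 tissue, meaning at least 2-fold higher than in each of the other tissues with both comparisons past the threshold, numbered 469 for heart, 156 for bone marrow and 154 for kidney. Genes lower than in both numbered 201, 321 and 167 in the same order. In heart cells the largest fitted smaller-of-both differences were those of Serpina3n (8.20), Serping1 (6.32), Slitrk5 (5.63), Cd55 and the integrin-like gene Itgbl1 (both 5.36) and Rspo3 (5.33). In bone marrow they were those of Ccl9 (3.99), Oasl2 (3.51), the RNA sensor gene Dhx58 (3.39), Dio3 (3.38), Rsad2 (3.36) and Rgcc (3.18). In kidney they were those of Emcn (3.99), H2-M1 (3.72), the phosphatase gene Ptprz1 (3.72), Dmrta2 (3.50), Pilra (3.43) and the natriuretic peptide gene Nppb (3.21). The fitted log2 differences of Serpina3n, Slitrk5, Cd55, Emcn, H2-M1 and Ptprz1 are set against a tissue with a mean below the detection floor, so neither they nor their rank are measured sizes. Without background correction, the counts of genes higher in 1 tissue were 267, 78 and 95 for heart, bone marrow and kidney, and with probes detected on all 12 arrays they were 224, 85 and 78. The counts of genes lower in 1 tissue were 101, 181 and 82 without background correction, in the same order, and 149, 188 and 130 with probes detected on all 12 arrays.

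Heart and kidney cells also differed from bone marrow MSC in the same direction for many genes. Higher in both were 1359 genes, and lower in both were 1564, against 491 called in opposite directions. Both comparisons use the same bone marrow arrays. In 20 simulations with no gene changed between tissues, the mean number called the same way in both was 0. With no gene changed, few calls can arise at the threshold. That 0 therefore cannot show how much the shared bone marrow arrays add to the overlap. Independent lists of the same sizes would share 566.7 higher and 775.2 lower genes. With the bone marrow arrays split between the comparisons, 1077 to 1157 were higher in both and 1129 to 1348 lower in both over 6 splits. The fold changes correlated at r = 0.5325 across genes, against 0.5006 in the simulations, and their covariance was 0.3137 against 0.0122 simulated, a difference of 0.301. The simulations hold no tissue differences, so a profile particular to bone marrow would alone raise the covariance. It would also raise the overlap above that of independent lists, and it remains when the bone marrow arrays are split. None of these values can therefore tell a departure shared by heart and kidney from one of bone marrow alone. Grb10, Mylk, Myh11, Hoxb2 and Itga11 were among the genes higher in both, and Ccl9, Oasl2, Rsad2, Lpl and Sp7 (-1.75 ± 0.15 in kidney) among those lower in both. Icam1, Thy1, Hoxc6 and Osr1 differed in how the tissues departed from bone marrow, as their kidney minus heart values given above show.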

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

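The tests of array brightness and of other cell types were chosen after the results had been seen, while the splits of the arrays were planned. For the numbers of differing genes, 1 of 35 splits of the 8 arrays, the real one, gave as many in each comparison. The numbers were 6042 in heart minus bone marrow, 4769 in kidney minus bone marrow and 5290 in kidney minus heart (highest other split 0 in each). The same holds at 2-fold or more (1512, 913 and 1168, highest other 0 in each). Splits that mix tissues count the tissue differences as spread, which lowers their numbers of calls. The 0 calls of the other splits therefore show that tissues differ, but not how many of the calls arose by chance. For gene lists the real split gave the most in heart minus bone marrow (9 lists, highest other 8) and kidney minus bone marrow (10, highest other 8). These leads are narrow, and 1 of 35 is the smallest share possible, so chance cannot be called excluded. In kidney minus heart (4, highest other 5) 10 of 35 splits gave as many. These counts are with the preset correlation, and with an estimated one 1, 3 and 1 lists passed, which was not tried on other splits. Of 100 groupings of the 12 arrays, out of 5775 possible, the real one alone gave as many genes differing between any tissues (7376, highest other 3866). The real grouping alone also gave as many genes higher in 1 tissue (779, highest other 529). It gave the most shared differences from bone marrow too (2923, highest other 0). Since mixed groupings count tissue differences as spread, these leads show only that tissues differ. They cannot decide whether heart and kidney share a departure from bone marrow.

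Interferon response genes were higher in bone marrow than in kidney cells by a median log2 of 2.46, which did not pass as a list with an estimated correlation (adjusted p = 0.277), and on bone marrow replicate 1 the median difference from the other bone marrow arrays was -1.85. An effect of array brightness depends on a probe's level. For 10000 random lists matched on mean expression the central 95% ranges were -0.2 to 0.25 and -0.21 to 0.18, so other genes of like level did not move with the list. Quantile normalization holds such matched lists near 0, and the interferon list was chosen for the test after its difference was seen. The test therefore cannot decide on brightness. Of 11 abundant macrophage markers, 0 were detected on any bone marrow array. These 11 were picked from a longer list after the values were known, so they cannot decide on macrophages in the bone marrow cultures. On the longer list 7 of 23 genes with a probe were detected on all 4 bone marrow arrays, and 7 each on all heart and all kidney arrays. Trem2 and Cd14, also on that list, were lower in kidney than in bone marrow cells, so single myeloid genes moved with the pattern. The other 6 of 8 tested members did not pass. In heart cells, where interferon response genes were also lower, 4 of the 8 were higher than in bone marrow and 2 lower. The mean log2 value of the macrophage list was 6.926 on bone marrow replicate 1, within the 6.84 to 6.984 of the other bone marrow arrays. An interferon response that varied between the bone marrow cultures may explain the pattern, and tissue of origin and culture state stay open and were not tested.

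Proliferation genes were lower in heart than in bone marrow cells by a median log2 of -1.17 (adjusted p = 0.0893 for the list with an estimated correlation), outside the central 95% of lists matched on mean expression (-0.29 to 0.21). Quantile normalization and the late choice of the list limit this test too, so it cannot decide on array brightness. Of 26 abundant markers of macrophages, endothelial cells and cardiomyocytes, 0 were detected on all 4 heart arrays. These 26 were picked from longer lists after the values were known, so they cannot decide on the share of those cells. On the longer lists 7 of 23 macrophage, 6 of 21 endothelial and 4 of 19 cardiomyocyte genes were detected on all 4 heart arrays. Members such as Esm1, Lyz2 and some cardiomyocyte genes were called higher in heart than in bone marrow cells, while 2 macrophage genes were lower. The largest rise among these cardiomyocyte genes was that of Nppb, whose mean log2 value was 6.94 in heart but 10.15 in kidney cells. The others were higher by a log2 of 0.495 or less, with heart and bone marrow arrays overlapping. Slower growth of the heart cultures may explain the fall, and tissue of origin, culture density and passage stay open and were not tested.

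In 36 of 441 groups of 4 arrays tested (8.2%), 1 array stood apart, with a gap to the nearest array that was large for the group's range by Dixon's test at the 95% level. Chance gives about 1 in 20 such groups, and 15 of the 36 concerned bone marrow replicate 1. Kidney replicate 3 had 19577 probes detected (others 19204 to 19245). The mean log2 value of the endothelial list was 6.88 on bone marrow replicate 2 (others 6.76 to 6.78), that of the marrow niche list 9.13 on bone marrow replicate 1 (others 9.31 to 9.33) and that of the Wnt list 7.73 on heart replicate 4 (others 7.96 to 8). On bone marrow replicate 1 the log2 value was Cck 5.46 (others 4.69 to 4.8), Cdkn1c 7.88 (others 6.92 to 7.05), Cxcl10 7.95 (others 8.55 to 8.64), Dio3 11.18 (others 12.1 to 12.26) and Ednrb 5.58 (others 7.09 to 7.36). Further values on bone marrow replicate 1 were Hgf 11.4 (others 11.9 to 11.94), Hoxa10 6.49 (others 6.8 to 6.87), Hoxb2 5.91 (others 5.24 each), Hp 8.11 (others 10.36 to 10.61) and Lpl 13.13 (others 14.01 to 14.17). Further values on bone marrow replicate 1 were Mylk 6.6 (others 7.93 to 8.07), Rgcc 10.88 (others 11.71 to 11.8), Rsad2 8.71 (others 9.92 to 10.09) and Timp3 11.88 (others 11.34 to 11.35). On bone marrow replicate 2 the log2 value was Htra1 11.55 (others 11.25 to 11.28). On heart replicate 1 the log2 value was Cdkn1c 8.05 (others 8.23 to 8.27), Des 8.02 (others 7.7 to 7.75) and Fst 13.33 (others 13.39 to 13.4). On heart replicate 2 the log2 value was H2-M1 4.65 (others 4.5 to 4.52) and Peg3 9.38 (others 9.13 to 9.17). On heart replicate 4 the log2 value was Ankrd1 13.13 (others 12.82 to 12.86) and Itga11 12.01 (others 12.46 to 12.55). On kidney replicate 1 the log2 value was Fosb 9.67 (others 10.21 to 10.26). On kidney replicate 2 the log2 value was Actg2 15.14 (others 15.34 to 15.36), Ebf1 9.57 (others 9.5 to 9.51), Flt1 10.77 (others 10.87 to 10.88) and Tcf21 5 (others 5.33 to 5.37). On kidney replicate 3 the log2 value was Fst 11.1 (others 11.24 each) and Ndrg1 7.67 (others 7.37 to 7.4). On kidney replicate 4 the log2 value was Cck 9.79 (others 9.28 to 9.35), Pcolce2 11.42 (others 11.32 to 11.33) and Tagln 13.13 (others 12.91 to 12.94).

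Some results moved in opposite directions from bone marrow in heart and kidney cells, with the kidney minus heart difference past limma's threshold. The Hox list of paralogue groups 6 to 13 did so (median log2 kidney minus heart 1.45), although its fall in heart did not pass with an estimated correlation (adjusted p = 0.0831). Of 491 such genes, 22 are named in the text. The fitted log2 difference, which is no measured size where the signal in 1 tissue lay below the detection floor, was positive for Col2a1 (3.05), Dmrta2 (4.35), Gbx2 (4.78), Hoxc10 (5.6), Hoxc6 (6.05), Hoxc9 (7.25), Htra1 (3.17), Mmp13 (3.04), Pcolce2 (4.61), Pilra (4.29), Rgs4 (4.89), Tgfb2 (2.06) and Wnt2 (2.9). It was negative for Ednrb (-5.87), Foxf1 (-3.16), Grem1 (-4.18), Ndrg1 (-2.44), Osr1 (-2.89), Osr2 (-3.14), Prrx1 (-1.92), Tbx4 (-5.5) and Thy1 (-2.63).

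Probes without a gene name stayed out of the gene counts, and 1627 of 3334 kept ones (48.8%) differed between tissues by limma's F test.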

How the results depend on the processing

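Leaving out bone marrow replicate 1 before normalization was chosen after seeing the data. The counts of differing genes ranged from 4997 to 6268 in heart minus bone marrow, 3572 to 5214 in kidney minus bone marrow and 4183 to 5794 in kidney minus heart over the settings that test genes. With each array left out in turn they were 5613 to 6122, 4244 to 5020 and 4819 to 5691, and 5118 (84.7%), 3728 (78.2%) and 4321 (81.7%) of the called genes were kept in all 12 refits, with 0 changes of sign. Without bone marrow replicate 1 from the start they were 6099, 4996 and 5694. Replicate number as a block gave 6009, 4737 and 5275. Signal over background limits the sizes of changes of dim genes. A block by chip was not run, since no chip barcodes were given in the sources used here.

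Without background correction, 899, 526 and 659 genes reached 2-fold in heart minus bone marrow, kidney minus bone marrow and kidney minus heart. Genes higher in 1 tissue were then 78, 267 and 95 for bone marrow, heart and kidney, genes lower in 1 tissue 181, 101 and 82, and the mean correlation was 0.947 for bone marrow and heart, 0.966 for bone marrow and kidney and 0.959 for heart and kidney. With normexp at offset 50, genes higher were 88 for bone marrow and 312 for heart, genes lower 118 for heart and 101 for kidney, and the correlations 0.945, 0.965 and 0.957. Added background compresses ratios, by construction. On the authors' deposited values the mean correlation was 0.989 within and 0.936 between tissues (0.921, 0.948 and 0.938), and the cause was not tested. Without the detection filter it was 0.973 between tissues (0.968, 0.978 and 0.975), and with probes detected on all 4 arrays of 1 tissue 0.927, 0.954 and 0.943, with other genes entering by construction. With probes detected on all 12 arrays, fewer genes were tested, 981, 581 and 726 reached 2-fold, 85, 224 and 78 were higher in bone marrow, heart and kidney, and 188 were lower in bone marrow. The mean of a gene's probes gave correlations of 0.93, 0.955 and 0.944, and the cause was not tested. Every kept probe on its own, which counts probes in place of genes, gave 9296 in heart minus bone marrow, 7993 in kidney minus heart, 11358 between any tissues and 312 lower in heart.

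For named genes 2442 refits in other settings kept direction and side of the threshold, 3 newly passed (Acta2 in 1, Cxcl12 in 2), 1 no longer passed (Fosb, kidney) and 2 reversed (Cxcl12). Without 1 array 2279 refits were unchanged and 1 newly passed (Cxcl12). For gene lists 1007 were unchanged, 17 newly passed and 5 no longer passed. Cxcl12 in heart minus bone marrow was -0.13 without passing (adjusted p = 0.595), but 0.64 with the mean of its probes, 1.07 on another probe, -0.32 with array weights and -0.42 without bone marrow replicate 1, all past the threshold, and the cause was not tested. Among all 404 gene and comparison pairs the naming rule allows, 19 of 10060 refits reversed, 17 of them with other probes and 2 on the deposited values. Of the 190 pairs named in the text, picked with these values known, Cxcl12 in heart was the only one to reverse.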

Other observations

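The test of lung or foregut mesenchyme was chosen after the result had been seen. Aqp1, a water channel gene, was higher than in bone marrow in both heart (5.34 ± 0.17) and kidney cells (3.06 ± 0.17), and lower in kidney than in heart (-2.28 ± 0.17). Timp3, which encodes a metalloprotease inhibitor, rose by 2.68 ± 0.10 in heart and 2.81 ± 0.10 in kidney cells, and the matrix glycoprotein gene Thbs1 by 2.58 ± 0.11 and 1.81 ± 0.11. Mmp3 was higher in heart cells than in bone marrow (3.00 ± 0.21) and Mmp13 lower (-2.71 ± 0.13). Col2a1, a cartilage collagen gene, was lower in heart (-0.97 ± 0.18) and higher in kidney cells (2.08 ± 0.18). Of 20 tested matrix protease genes, 8 were higher and 6 lower in heart, and 10 and 4 in kidney (adjusted p for the lists 0.408 and 0.149).

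Immediate early and stress genes were higher for 9 of 19 members and lower for 4 in heart cells relative to bone marrow (adjusted p = 0.17), and higher for 8 and lower for 3 in kidney cells (adjusted p = 0.0967). Fosb rose by 1.91 ± 0.14 in heart and 1.77 ± 0.14 in kidney cells and the phosphatase gene Dusp1 by 1.50 ± 0.08 and 1.09 ± 0.08, although another kept Fosb probe gave 0.28 in kidney (adjusted p = 0.124), while Egr2 fell in heart cells (-1.59 ± 0.14). Of 14 marrow niche genes, 8 were higher and 5 lower in heart (adjusted p = 0.608), and 3 were higher and 8 lower in kidney (adjusted p = 0.27). The mesenchymal factor gene Prrx1 rose in heart cells (1.41 ± 0.09), and the B-lineage and niche factor gene Ebf1 fell (-1.45 ± 0.08). Ribosomal protein genes changed little, with 6 of 20 lower in heart and 4 in kidney, none higher and none by 2-fold (median log2 -0.03 in both). The list did not pass camera (adjusted p = 0.48 in heart and 0.397 in kidney) but passed fry (adjusted p = 0.0138 and 0.0204).

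Tbx4 and Fgf10, which act in lung bud mesenchyme, were higher in heart than in kidney cells, and the foregut mesenchyme genes Barx1 and Foxf1, chosen after their values were seen, were higher than in bone marrow (at least 19-fold and 2.26 ± 0.12). A candidate explanation is lung or foregut mesenchyme among the heart cultures, tested on 9 marker genes, Foxf1 among them, with a named probe. Of these, 1 was detected on all heart arrays and higher than in kidney, namely Foxf1 itself (kidney minus heart -3.16 ± 0.12), while Wnt2 was detected on 0 heart arrays. The condition first written against this explanation, few markers and either Foxf1 or Wnt2 undetected, was met through Wnt2, whose value was already known. Foxf1 went the other way, but it is part of the pattern to be explained and adds no separate evidence. With both values known beforehand the markers decide neither way. Heart origin and lung or foregut origin of these genes cannot be told apart.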
